A study of Homo sapiens with 6 samples.

How the data were processed

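RNA was measured by sequencing in MCF-7:5C cells, an estrogen receptor-positive breast cancer line derived from MCF-7 by growth without estrogen. The 6 groups of the labels held 1 library each: vehicle (0.1% ethanol), 17β-estradiol (E2, 1 nM), 4-hydroxytamoxifen (4-OHT, 1 µM), E2 plus 4-OHT, the Src family kinase inhibitor PP2 (5 µM), and E2 plus PP2. Treatment lasted 72 h, per the labels' protocols. RNA was taken up in TRIzol, cleaned on RNeasy Micro columns and sequenced as paired-end reads of 100 bases on an Illumina GAII, per the labels' protocols. How ribosomal RNA was kept out is not given in the sources used here.

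The authors deposited 1 table per library with FPKM values (fragments or reads per kilobase of gene model per 1000000) for 36953 Ensembl gene identifiers. TopHat 1.3.0, Cufflinks 1.0.3, Cuffdiff 1.1.0 and the genome builds hg19 and hg18 are named, per the submitters' processing notes, which give neither their roles nor their order. Which reads made up the 1000000, whether strand was used and how reads matching several places were shared are not given in the sources used here. The deposited FPKM summed to between 3957806 and 4037092 per library, so they were used as relative levels. An exact 0 in such a table can be a failed estimate: PPIA, a gene every cell uses, was listed at 0 in 3 libraries, and RPL3 and RPL7 were far below other ribosomal protein genes. A gene at 0 is therefore described as listed at 0, without a fold.

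Each table's value column carried the whole title of exactly 1 sample, and in 6 of 6 tables that was a sample other than the one the archive record attached the table to. By a rule written before the data were examined, and without use of the values, each library was given to the sample that its column names. The archive record was run as an alternative for the counts of 2-fold genes, the estrogen-induced list and the measures of the E2 response beside an inhibitor, and it moved or reversed nearly all of these. The other 23 lists were not run under it. As a check of the link, the median FPKM of 39 estrogen-induced genes fixed in advance was 47.1 in the vehicle library, 242 with E2, 123 with 4-OHT, 125 with E2 plus 4-OHT, 77.8 with PP2 and 234 with E2 plus PP2. Every direction given for a treatment rests on this link.

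Symbols came from a table of gene identifiers and names and then from GENCODE release 29. They were found for 24621 identifiers, which made 23890 symbols, and the values of 15 symbols that stood on several identifiers were summed. The 12332 unmatched identifiers held between 4.08% and 4.49% of the summed FPKM and entered no list. No genomic coordinates are printed, because the build behind the gene models was not stated and the reference at hand is on another build than those named. Genes are identified by symbol and, for those that lead a comparison, by their Ensembl identifier.

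Depth was compared from the low values. Below 1 FPKM, between 47.1% and 52.8% of 2412 to 3078 genes per library pair had ratios that matched a ratio of whole numbers up to 6 times 1 common factor, within 0.0004 on the log2 scale. That factor put the depth at 1.0 for E2, 0.745 for 4-OHT, 0.883 for E2 plus 4-OHT, 0.703 for PP2 and 0.677 for E2 plus PP2, relative to the vehicle library. Absolute totals were not recovered. In 338 genes at equal small values in the vehicle and E2 libraries the median was 0.127 FPKM. If that is 1 read, 1 FPKM stands for about 8 reads and 5 FPKM for about 39, and the counting error of a ratio of 2 values of 5 FPKM is 0.33 on the log2 scale. In 6 simulated libraries of 36953 genes the relative depths came back with an error of 0.0%. Those libraries were built from whole-number reads times 1 factor per library, as the method assumes. They check the search and not how well the deposited values meet that assumption.

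With 1 library per group there was no replicate check, no test and no p-value, and each comparison describes 2 libraries. The log2 ratio of (FPKM + 1) was computed for genes at 1 FPKM or more in either library. A fold on this scale understates the difference for low genes. Genes at least 2-fold higher or lower on it (log2 ratio of 1) were counted. A median over a gene list was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and its percentile among them describes these libraries alone, since genes are not replicates. In simulated libraries with the vehicle library's levels (13362 genes), 2.0% of 100 unchanged lists of 20 genes lay outside the central 95%. A list raised 2-fold lay at percentile 100, and the median log2 ratio of 100 genes raised 2-fold and of 100 raised 4-fold came out at 1.0 and 1.99. These simulated libraries held counting noise alone, without differences between cultures or members that vary together. The 2.0% therefore does not give the rate at which unchanged lists stand apart in real libraries.

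The comparisons were E2, 4-OHT and PP2 against vehicle, E2 plus each inhibitor against that inhibitor, and E2 plus each inhibitor against E2. Those against vehicle share the vehicle library, and those against E2 share the E2 library with each other and with E2 against vehicle, so similarities between them are not read as shared effects. E2 plus PP2 over PP2 shares the PP2 library with PP2 over vehicle, and E2 plus 4-OHT over 4-OHT likewise shares the 4-OHT library, so a low value in that library lowers the one ratio and raises the other. How much of the E2 difference stood beside an inhibitor was measured by the slope through 0 and the Pearson correlation, across genes, of the ratio with inhibitor on that without. The share of 2-fold genes that were 2-fold the same way was also counted. These ratios share no library, but the values of the inhibitors share the E2 and vehicle libraries.

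Before the data were examined, 24 gene lists with 529 members were fixed: estrogen-induced, estrogen-repressed, ATF4-CHOP stress, endoplasmic reticulum chaperone and XBP1, oxidative stress, pro-apoptotic BCL2 family, survival BCL2 family and inhibitors of apoptosis, TNF family and extrinsic pathway, NF-kB and inflammatory, interferon-stimulated, cell cycle and DNA replication, Src family and adhesion, growth factor early response, growth factor receptors, p53 targets, aryl hydrocarbon receptor targets, sterol synthesis, fatty acid synthesis and lipid storage, luminal identity, basal and mesenchymal, markers of other cell types, hypoxia and glycolysis, cytosolic ribosomal proteins, and reference genes. The 14 members TNF, LTA, LTB, CCL5, TXNIP, SRXN1, UHRF1, LYN, ITGB3, ETV5, ACACA, PECAM1, HBB and HMBS were not analysed here. The lists overlap in some members, such as STC2, VEGFA, FAS and ERBB2.

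Genes were named by a rule fixed at the same time. It took, among genes at 5 FPKM or more in either library, the 8 with the largest and the 8 with the smallest log2 ratio, leaving out mitochondrial genes and small RNAs by a fixed set of symbol starts. The symbol Y_RNA, also a small RNA, was not covered by that set and stayed among the 8 lowest for E2 plus 4-OHT over 4-OHT. It added up to 4 members per list and direction at least 2-fold apart, the member farthest from 0 of a list with none, and ESR1, PGR and SRC. Other genes named for context were chosen after their values were seen: DDIT3 for E2 over vehicle, PRSS23 for 4-OHT over vehicle, PRSS23 and BCL2L11 for E2 plus 4-OHT over 4-OHT, GREB1 and DDIT3 for E2 plus PP2 over E2, and the 12 genes drawn as bars.

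The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, ratios centred on their median, values rescaled to a sum of 1000000, values rescaled to the same upper quartile of genes above 0, the highest identifier per symbol in place of the sum, and the archive record of the link. Scaling to the same upper quartile moved the median log2 ratio of all genes by 0.129 for E2 against vehicle and by -0.186 for E2 plus 4-OHT against E2, and the other rescalings moved it by less than 0.1 in each comparison. Shares that were kept beside an inhibitor were also taken over genes picked in the pair of libraries with the inhibitor, a setting chosen after the data were seen. The work used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.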

Results

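RNA was sequenced from MCF-7:5C cells after 72 h with vehicle, 17β-estradiol (E2), the antiestrogen 4-hydroxytamoxifen (4-OHT), the Src family kinase inhibitor PP2, or E2 together with either inhibitor. Each of the 6 groups held 1 library. MCF-7:5C is a subline of the estrogen receptor-positive breast cancer line MCF-7 that grows without estrogen and in which E2 is known to bring on apoptosis. The comparisons ask what each agent did alone and how much of the E2 response stood beside either inhibitor. Between 14503 and 15252 gene identifiers per library reached 1 FPKM, and depth relative to the vehicle library ran from 0.677 with E2 plus PP2 to 1.0 with E2. There was no replicate check, so every difference is one between 2 libraries. Fold values are on the log2(FPKM + 1) scale, which understates the difference for low genes. Libraries were assigned by the sample title each table carries. Under the archive's own record the median log2 ratio of 39 estrogen-induced genes, E2 over vehicle, would be -0.68 in place of 1.80, and it would be -1.24 in place of 1.54 for E2 plus PP2 over PP2.

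With E2 alone, textbook estrogen-responsive genes stood far above the vehicle level. PRSS23, a serine protease gene (ENSG00000150687), was at 505 FPKM with E2 and 1.247 with vehicle (log2 ratio 7.82). GREB1, an estrogen receptor cofactor (ENSG00000196208), was at 2500.0 against 77.04 FPKM (log2 ratio 5.00). PGR, the progesterone receptor (ENSG00000082175), was listed at 0 with vehicle and was at 12.1 FPKM with E2. EGR3, an early growth response factor, and PDZK1, a scaffold protein, had log2 ratios of 5.76 and 5.78. Of 39 estrogen-induced genes fixed in advance, 26 were at least 2-fold higher and 2 were at least 2-fold lower, RET (-3.15) and TFF3 (-1.34). Their median log2 ratio of 1.80 lay at percentile 100 among matched random lists. The largest ratios also included the adhesion protein gene CLMP (7.25), complement C3 (6.68), the calcium-binding CALB2 (6.58) and TGM2, a protein cross-linking enzyme (6.52). SLC2A14 (6.21) is nearly identical to SLC2A3, so its reads may belong to either.

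Luminal genes were lower with E2. ESR1, the estrogen receptor itself (ENSG00000091831), was at 198 FPKM against 969 with vehicle (log2 ratio -2.29). SPDEF, an ETS factor of luminal cells (ENSG00000124664), was at 39.7 against 1775 FPKM (-5.45), and FOXA1, a pioneer factor for the receptor, had a log2 ratio of -1.71. In all, 7 of 17 luminal identity genes were at least 2-fold lower and 0 were higher (median -0.76, percentile 0.0). Of 12 measured basal and mesenchymal genes 8 were at least 2-fold higher (median 1.61, percentile 100). Among them were SERPINE1, an inhibitor of plasminogen activators (5.47), the transcription factor SNAI1 (3.87) and the smooth muscle actin ACTA2 (3.07), while TWIST1 was lower (-2.79). The list was low with vehicle, where its 20 matched members had a median of 0.55 FPKM, against 8.1 with E2. FGFR4, a fibroblast growth factor receptor, and ERBB2 were lower (-4.07 and -2.06), and IRS1 and IGF1R of the insulin-like growth factor axis were higher (2.96 and 2.61). The calcium-binding PVALB (ENSG00000100362) had the lowest ratio, at 0.470 FPKM with E2 and 212 with vehicle (-7.18). DLK1 and MEG3, neighbours of 1 imprinted locus, were also among the 8 lowest, at -5.67 and -5.43.

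Stress, inflammation and death genes were higher in part. BCL2L11, which encodes the killer protein BIM (ENSG00000153094), was at 488 FPKM with E2 and 104 with vehicle (2.21), and PMAIP1 and BBC3, which encode NOXA and PUMA, had log2 ratios of 2.17 and 1.62. The whole list of 21 pro-apoptotic genes had 3 members at least 2-fold higher and 1 lower, with a median of -0.12 and a mean of 0.17. That median turned to 0.01 with the same upper quartile. Of 20 p53 targets 12 were at least 2-fold higher (median 1.04, percentile 100), led by GDF15 (2.21) and the death receptor gene FAS (2.17). Of 16 measured NF-kB and inflammatory genes 9 were at least 2-fold higher (median 1.55, percentile 100), including TNFAIP3, a brake on NF-kB (3.49), and RELB (2.23). The 26 matched members of that list had a median of 1.92 FPKM with vehicle and 14.7 with E2. HMOX1, heme oxygenase of the oxidative stress response (ENSG00000100292), was at 213 against 19.8 FPKM (3.37), and the chaperone HSPA5 had a log2 ratio of 1.41. Of 19 ATF4-CHOP stress genes 7 were at least 2-fold higher and 0 lower (median 0.19, percentile 97.7), with INHBE at 3.68 and PPP1R15A at 2.64, whereas DDIT3, the gene of CHOP itself, was at 602 against 549 FPKM. Early response genes were at least 2-fold higher in 10 of 25, led by FOS (4.23) and FOSL1 (3.65), and lower in 2, DUSP4 (-1.73) and SPRY1 (-1.22).

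Cell cycle genes were slightly lower with E2, with a median log2 ratio of -0.28 over 34 genes (percentile 0.18). The 4 at least 2-fold lower were CCNE2 (-2.74), RRM2 (-1.50), E2F1 (-1.46) and E2F2 (-1.35). Ribosomal protein genes were higher in 30 of 30 members by a small amount (median 0.29), and the median kept its sign under every scaling tried. In all, 1675 of 13989 genes were at least 2-fold higher and 726 were at least 2-fold lower with E2. With a pseudocount of 5 the number higher was 899, and with values summing to 1000000 it was 970.

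**Figure D1:**
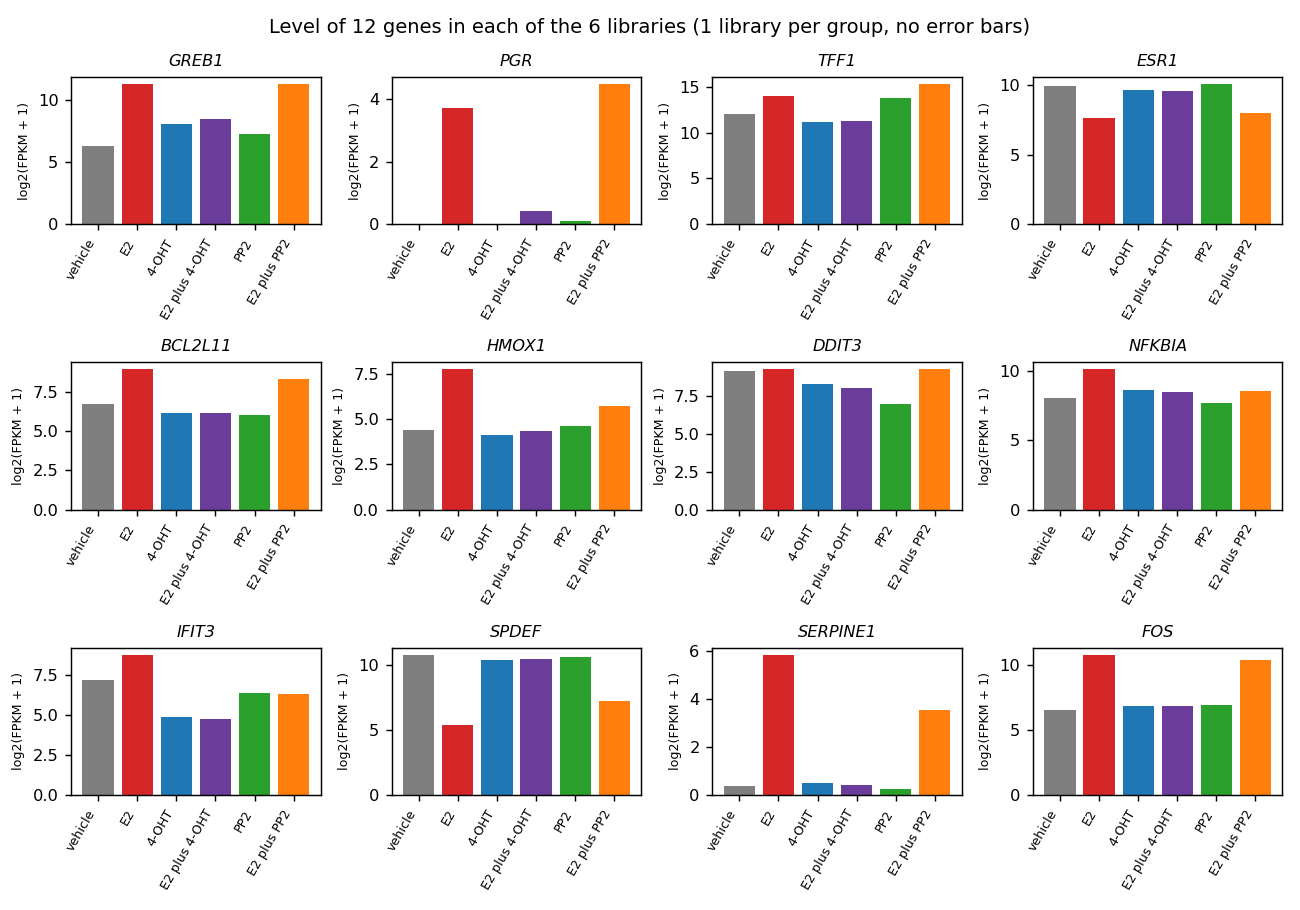
Bars show log2(FPKM + 1) of 12 genes in each of the 6 libraries, with 1 library per group and no error bars. GREB1 stands at 2500.0 FPKM with E2, 2442 with E2 plus PP2 and 347 with E2 plus 4-OHT, and IFIT3 at 148 with vehicle and 27.9 with 4-OHT.

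With 4-OHT alone, interferon-stimulated genes were lower. Of 34 measured, 34 were below the vehicle level and 24 at least 2-fold so, with a median log2 ratio of -1.64 (percentile 0.0). IFIT3, an antiviral effector (ENSG00000119917), was at 27.9 FPKM against 148 with vehicle (-2.36), and OASL, IFI44L and HERC6 had log2 ratios of -2.42, -2.45 and -2.45. IRF1, a transcription factor of the same response, was at -1.83. Cell cycle genes were lower in 34 of 34 (median -0.54, percentile 0.0), but only CCNE2 reached 2-fold (-1.06). Among early response genes 7 of 24 were at least 2-fold lower, including DUSP4 (-1.80), KLF4 (-1.75), EGR1 (-1.68) and JUN (-1.58), and 3 were higher, led by SPRY4 (2.09).

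Several estrogen-induced genes were higher with 4-OHT than with vehicle. The same vehicle library stands under E2 over vehicle, so this is not read as an effect shared with E2. PDZK1, AGR2 (a secretory pathway disulfide isomerase) and EGR3 had log2 ratios of 4.71, 4.25 and 4.06, and 16 of 37 list members were at least 2-fold higher (median 0.68, percentile 100). With members at 5 FPKM or more that median was 1.14. PRSS23 and PGR did not follow: PRSS23 was at 0.975 FPKM and PGR was listed at 0. The largest ratio was that of PGLYRP2, a peptidoglycan-degrading enzyme (ENSG00000161031), at 971 FPKM against 2.61 (8.07). The keratin KRT13 (7.81), the prostaglandin E synthase PTGES (5.65) and the gastric proton pump subunit ATP4A (5.73) were also among the 8 largest, as were SERPINA1 (5.81) and TGM2 (6.07). The glucose transporter SLC2A1 (2.17) and the lipogenic THRSP (4.08) were also higher, and sterol synthesis genes were slightly higher as a list (16 of 22 above 0, median 0.22). PDE4B, a cyclic AMP phosphodiesterase, and the dopamine receptor DRD1 had the lowest ratios (-3.56 and -3.48). ESR1 was near its vehicle level (-0.22), as was SRC (0.06). Overall counts were 476 genes at least 2-fold higher and 502 lower of 13496, against 252 and 269 with a pseudocount of 5 and 289 and 286 with values summing to 1000000.

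With PP2 alone, ATF4-CHOP stress genes were lower. DDIT3 (ENSG00000175197) was at 121 FPKM against 549 with vehicle (-2.17), and INHBE, ATF3 and CEBPB had log2 ratios of -1.55, -1.44 and -1.23. Of 19 list members 9 were at least 2-fold lower and 17 were below 0 (median -0.96, percentile 0.0). NUPR1, another stress-response gene, was at 128 against 733 FPKM (-2.51), and ERN1, the stress sensor IRE1, was at -1.45. ERN1 was the lowest member of the endoplasmic reticulum chaperone and XBP1 list. That list went the other way, with 16 of 23 above 0 (median 0.175, percentile 99.8). Early response genes were lower as a list (median -0.36, percentile 0.0), with EGR1 at -1.70, JUN at -1.32 and DUSP5 at -1.26, while PHLDA1 was higher (2.19). Interferon-stimulated genes were lower in 30 of 34 (median -0.56, percentile 0.0), 3 of them at least 2-fold.

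Some estrogen-induced genes were higher with PP2: TFF3 (2.83), the chemokine CXCL12 (2.37), the small heat shock protein HSPB8 (1.84) and TFF1 (1.72), a trefoil peptide at 13880.0 FPKM against 4211. With E2 over vehicle TFF3 was lower (-1.34), while CXCL12, HSPB8 and TFF1 were higher. Of 37 members, 9 were at least 2-fold higher (median 0.48, percentile 100). Estrogen-repressed genes were below the vehicle level in 15 of 18 (median -0.50, percentile 0.0). Of these 18 genes 3 were at least 2-fold lower, with BIK at -1.84, and 2 were higher, CYP1B1 (1.20) and PDCD4 (1.09). With E2 over vehicle that list went both ways, with 4 of 18 at least 2-fold higher and 5 lower (percentile 3.11). Cell cycle genes were above the vehicle level in 29 of 34 (median 0.29, percentile 100), with CCNE1 at 1.02, and sterol synthesis genes in 21 of 22 (median 0.28, percentile 100), with MSMO1 at 1.101. CGA, the shared subunit of the glycoprotein hormones (ENSG00000135346), had the largest ratio, at 1530.0 FPKM against 73.2 (4.37), followed by the sulfate transporter SLC26A2 (3.29). EFHD1, a mitochondrial calcium-binding protein gene (ENSG00000115468), was lowest, at 13.6 against 155 FPKM (-3.41). The linker histone H1-3 was also lower (-2.77), as were H2AC9P and H1-12P (-2.99 and -2.71), histone pseudogenes that share sequence with other histone genes. SRC, a target of the inhibitor, was at 14.1 FPKM against 12.9 (0.12), and the median of the Src family and adhesion list was 0.02, or -0.01 with the same upper quartile. Only 259 genes were at least 2-fold higher and 257 lower of 13369, which became 105 and 127 with a pseudocount of 5, and 437 and 403 with 0.1.

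Beside 4-OHT, the difference that went with E2 was small. In the central 95% of 11640 genes at 5 FPKM or more, the log2 ratio of E2 plus 4-OHT over 4-OHT ran from -0.26 to 0.27. Over E2 against vehicle the same range was -1.50 to 2.35. PRSS23 was at 0.966 FPKM with both and 0.975 with 4-OHT, and BCL2L11 at 70.5 and 71.2. Of 35 estrogen-induced genes 0 reached 2-fold, and their median was 0.08 (percentile 100). ATF4-CHOP stress genes were slightly lower (16 of 19, median -0.18, percentile 0.0), with CHAC1 at -0.45. Cell cycle genes were slightly higher (31 of 34, median 0.08, percentile 100), with CCNE1 at 0.39. The largest ratios lay at low values. Most of the lower ones and some of the higher ones were in pseudogenes, where reads can belong to another copy. FABP6 was at 16.05 FPKM with both and 7.87 with 4-OHT (0.94). LGALS1, a galectin, was at 2.45 against 7.84 FPKM (-1.36), TNNC1 was at 5.16 against 1.88 (1.096), and GMFG was at 6.01 and listed at 0 with 4-OHT. At 1 FPKM or more, 77 genes were at least 2-fold higher and 89 lower of 13452, and at 5 FPKM or more 8 and 14. Across genes the slope on the E2 ratio without inhibitor was 0.02 and Pearson's r was 0.09. Of 1675 genes higher with E2 alone 0.657% were at least 2-fold higher beside 4-OHT, and of 726 lower 0.964% were lower. That is 11 and 7 genes, against 10 and 6 that were 2-fold apart the opposite way, and among the 13989 genes compared for E2 over vehicle the shares were 0.293% and 0.357%. The kept shares were 6.14% and 3.11% with a pseudocount of 0.1, and 0.0% with 5. With genes picked in the pair with 4-OHT instead, 14.3% of 77 higher and 7.87% of 89 lower genes were so without it, against 9.69% and 5.20% of all genes in that pair.

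Set against E2 alone, the library with E2 plus 4-OHT had lower PRSS23 (-8.01), lower CLMP (-6.65), lower SERPINE1 (-5.42) and lower CYP24A1, the vitamin D hydroxylase (-5.04). It had higher SPDEF (5.07), higher HMGCS2, a ketone body synthesis enzyme (6.76), and higher CITED1, a transcriptional co-regulator (5.10). BCL2L11 was at 70.5 FPKM against 488 (-2.77), PMAIP1 at -2.95 and HMOX1 at -3.43. Of 34 interferon-stimulated genes 26 were at least 2-fold lower (median -2.12, percentile 0.0), with HERC5 at -4.64 and IFIT3 at -4.06. At least 2-fold lower were also 12 of 20 p53 targets (median -1.12), with GDF15 at -2.97, and 9 of 16 NF-kB genes (median -1.23), with TNFAIP3 at -4.12 and SOCS3 higher (1.56). Luminal genes were at least 2-fold higher in 7 of 17 and lower in 1 (median 0.75), with ESR1 at 773 against 198 FPKM (1.96). Among estrogen-induced genes 19 of 39 were at least 2-fold lower and 5 higher (median -0.92), the latter including RET (4.26) and AGR2 (2.32). In total 679 of 14037 genes were at least 2-fold higher and 1664 lower, the latter 921 with a pseudocount of 5 and 998 with values summing to 1000000.

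Beside PP2, E2 went with a large difference. Over PP2 alone, PRSS23 was at 821 FPKM against 2.11 (8.05), PGR at 21.3 against 0.0684 (4.38), and 25 of 39 estrogen-induced genes were at least 2-fold higher and 3 lower (median 1.54, percentile 100). After PRSS23 the largest ratios were those of the protease inhibitor SLPI (6.60), C3 (6.57), CLMP (6.53), the neurturin receptor GFRA2 (6.02) and the spermine oxidase SMOX (5.95). ATF4-CHOP stress genes were at least 2-fold higher in 13 of 19 and lower in 1 (median 1.43, percentile 100), with INHBE at 5.00, SLC7A11 at 2.14 and DDIT3 at 606 against 121 FPKM (2.31). The comparison rests on the same PP2 library in which this list was low against vehicle (-0.96), so that library alone may account for a median above that of E2 over vehicle (0.19). BCL2L11 (2.32), PMAIP1 (2.45) and BBC3 (1.58) were higher. The whole list of 21 pro-apoptotic genes did not stand apart (median 0.12, percentile 78.4). Of its members 3 were at least 2-fold higher, 0 were so lower, and 10 were below 0. At least 2-fold higher were also 7 of 16 NF-kB genes, with 1 lower (median 0.91, percentile 100) and 7 of 20 p53 targets (median 0.75, percentile 100). Cell cycle genes were at least 2-fold lower in 10 of 34 (median -0.70, percentile 0.0), with CCNE2 at -2.56, E2F1 at -1.88 and PCNA at -1.34. The same PP2 library was high for the cell cycle list against vehicle (0.29). That library alone may account for a cell cycle median below that of E2 over vehicle (-0.28). ESR1 (-2.08), SPDEF (-3.35) and FGFR4 (-3.81) were lower, and CLEC3A, a lectin gene, was lowest (-5.93). In all 1340 of 13864 genes were at least 2-fold higher and 686 lower, or 731 and 452 with a pseudocount of 5.

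Across 13989 genes the ratio of E2 plus PP2 over PP2 had a slope of 0.71 on that of E2 over vehicle, and Pearson's r was 0.79. Genes are not replicates, but these ratios share no library. Error in the ratio without inhibitor pulls the slope toward 0, so 0.71 is not the share of the E2 response kept. At 5 FPKM or more the standard deviation of the ratios was 0.815 for E2 plus PP2 over PP2 and 0.908 for E2 over vehicle. Of the 1675 genes higher with E2 alone 54.8% were at least 2-fold higher beside PP2, and of the 726 lower 56.3% were lower. Among all genes 9.23% and 4.80% were. The median log2 ratio of the 1675 genes was 1.12 with PP2 and 1.51 without. Picking genes by their ratio in the first pair lowers their ratio in the second by selection alone. When they were instead picked in the pair with PP2, 68.5% of 1340 were also higher without it, and their median was 1.479 with PP2 and 1.42 without. Of 686 lower genes picked so, 59.6% were also lower without it, with medians of -1.34 with PP2 and -1.22 without. Among all genes in that pair the shares were 11.3% and 5.09%.

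**Figure D2:**
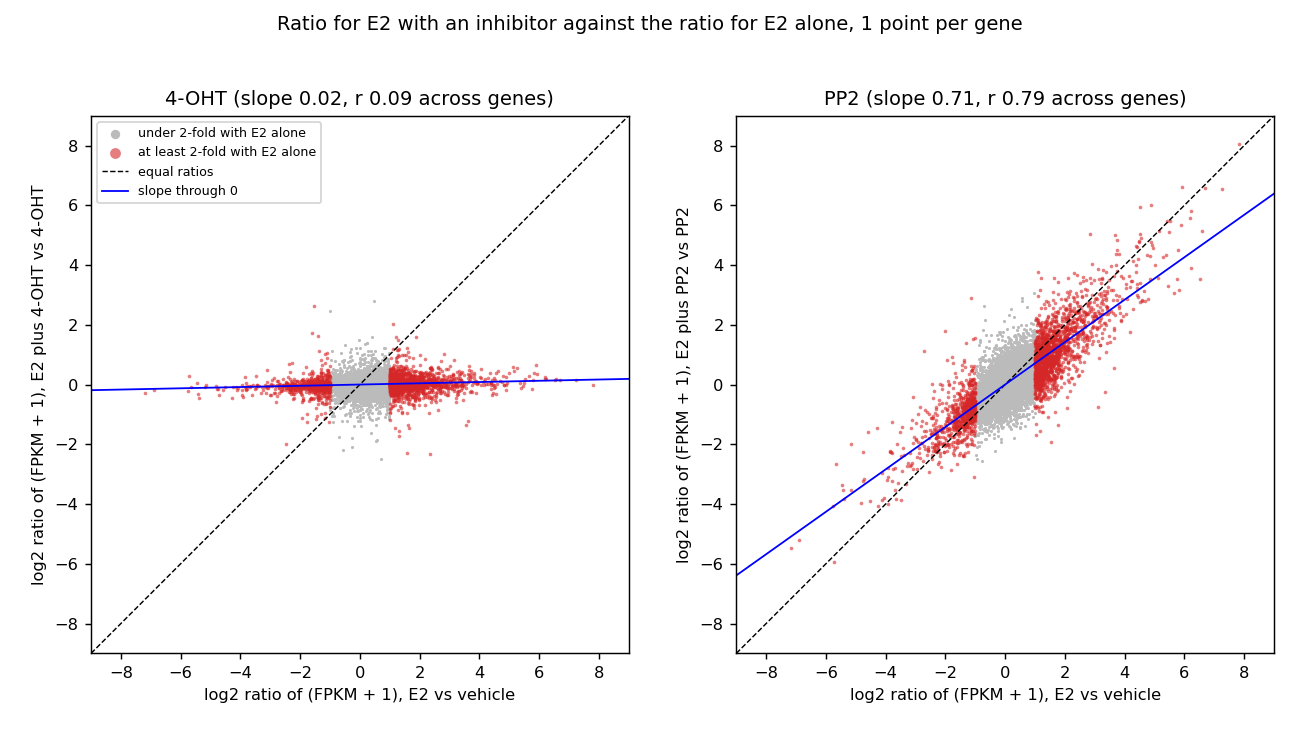
Each point is a gene, with its log2 ratio of (FPKM + 1) for E2 over vehicle on the x axis and for E2 plus inhibitor over inhibitor on the y axis, and genes at least 2-fold apart with E2 alone in red. The slope through 0 is 0.02 for 4-OHT and 0.71 for PP2, beside the dashed line of equal ratios.

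Set against E2 alone, E2 plus PP2 went with lower inflammatory, interferon and early response genes. Interferon-stimulated genes were at least 2-fold lower in 17 of 35 and higher in 1 (median -0.95, percentile 0.0). IFIT3 was at 80.0 FPKM against 443 (-2.45), IFIT2 at -2.44, and the type III interferons IFNL1 and IFNL2 at -2.79 and -2.53. NF-kB genes were below the E2 level in 14 of 16, 5 of them at least 2-fold (median -0.63, percentile 0.0), with TNFAIP3 at -1.87 and NFKBIA, the NF-kB inhibitor, at -1.60. Early response genes were below it in 19 of 25, 9 of them at least 2-fold (median -0.63, percentile 0.0), with ETV4 at -2.03, FOSB at -1.91 and FOSL1 at -1.68. TP63, a p53 family member (ENSG00000073282), was at 17.3 against 120.0 FPKM (-2.73), HMOX1 at 50.8 against 213 (-2.05), and SERPINE1 at -2.30. For p53 targets 19 of 20 were below the E2 level and 0 reached 2-fold (median -0.30, percentile 0.0). Pro-apoptotic genes were below that level in 17 of 21 (median -0.18, percentile 0.22), with BBC3 lowest (-0.88). Reference genes were below it in 10 of 13 too (median -0.21, percentile 0.05). Small medians such as those of p53 targets and pro-apoptotic genes may therefore not be particular to these lists. The E2 library was high for NF-kB genes against vehicle (1.55), and that library alone may account for the NF-kB median of -0.63. PP2 over vehicle, which shares no library with this pair, had an NF-kB median of -0.05 (percentile 25.1). Interferon-stimulated and early response genes were lower there (-0.56 and -0.36).

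Estrogen-induced genes were not lower as a list with PP2 added (median 0.17, percentile 100). GREB1 was at 2442 against 2500.0 FPKM (-0.03), and 5 of 39 were at least 2-fold higher, including AGR2 (2.20), CXCL12 (2.07) and TFF1 (1.296), with PDZK1 lower (-1.06). Estrogen-repressed genes were below the E2 level in 15 of 18 (median -0.34, percentile 0.0), and 0 reached 2-fold. Reference genes had a median of -0.21 in the same comparison. ATF4-CHOP stress genes were near the E2 level (median -0.08), except PPP1R15A (-1.57), and DDIT3 was at 606 against 602 FPKM. Endoplasmic reticulum chaperone and XBP1 genes were above it in 22 of 23 (median 0.26, percentile 100), with EIF2AK3, the stress sensor PERK, at 0.85. The largest ratios were SCARA5, a scavenger receptor (3.59), CPS1 of the urea cycle (2.95) and SHH, a developmental signal (2.87). FOXI1 was the lowest (-2.86). Of 13967 genes 163 were at least 2-fold higher and 258 lower, or 69 and 113 with a pseudocount of 5, and 272 and 467 with 0.1.

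**Figure D3:**
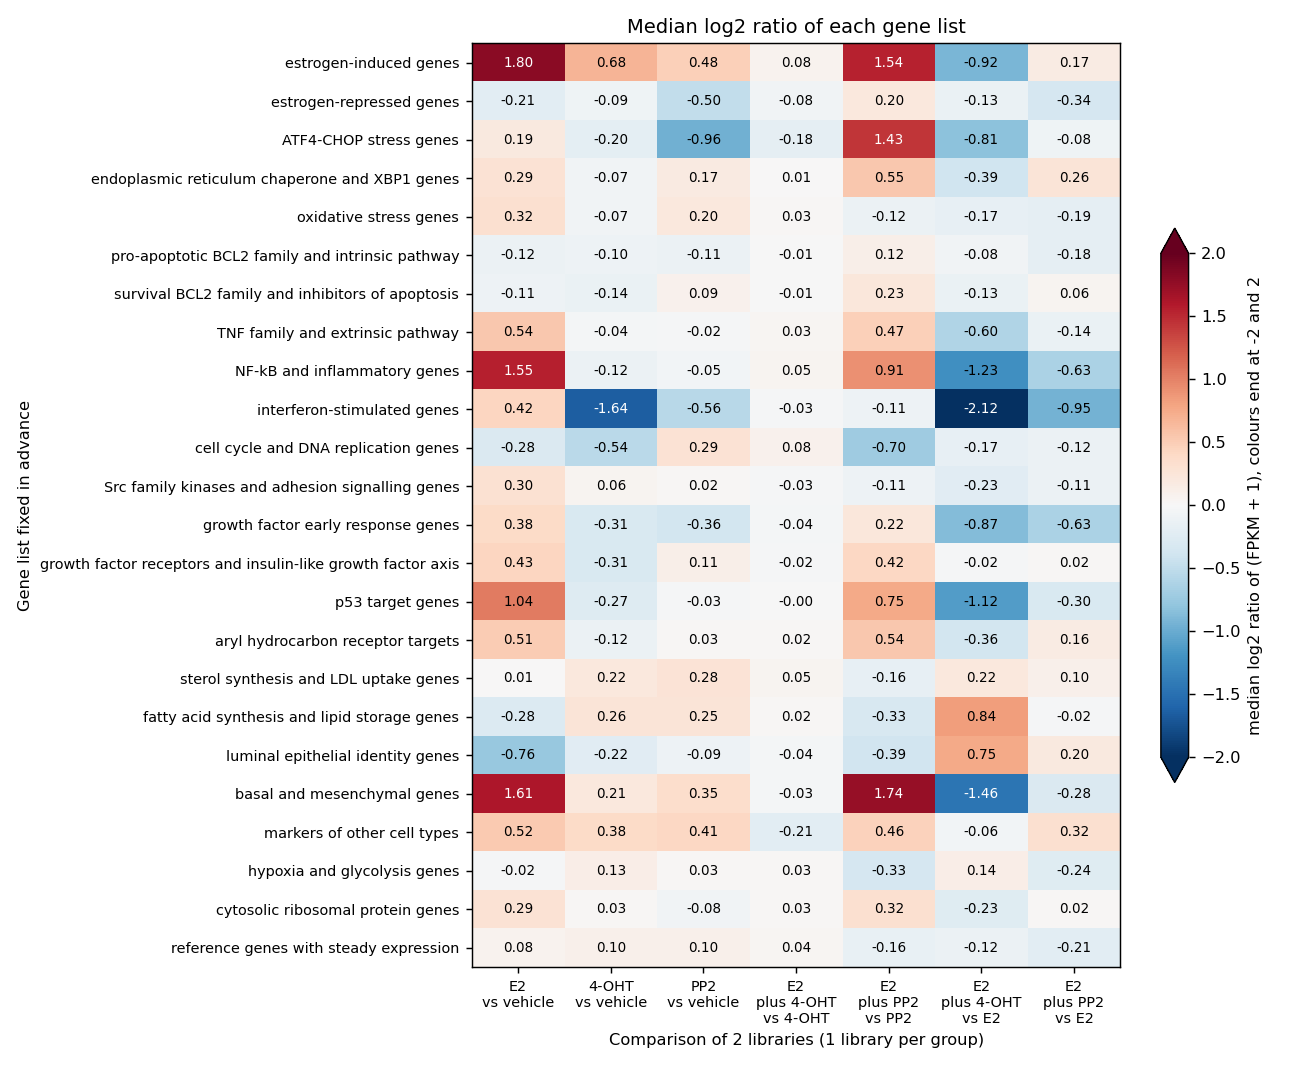
Each cell gives the median log2 ratio of (FPKM + 1) of a gene list fixed in advance in 1 of 7 comparisons of 2 libraries, with red above and blue below 0. Interferon-stimulated genes stand at -1.64 for 4-OHT over vehicle and ATF4-CHOP stress genes at -0.96 for PP2 over vehicle, and medians within 0.14 of 0, and those of markers of other cell types, can turn sign with the scaling.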

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

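The tests on the interferon-stimulated and ATF4-CHOP lists were chosen after their results were seen, and those on the link of libraries to samples before.

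For 3 gene lists the median log2 ratio for E2 had opposite signs beside 4-OHT and without it and lay outside the central 95% of random lists in both, and the differences were not tested. Other lists had opposite signs too, with at least 1 of the medians inside that range. ATF4-CHOP stress genes were at -0.18 for E2 plus 4-OHT over 4-OHT and 0.19 for E2 over vehicle. Interferon-stimulated genes were at -0.025 and 0.42. Cell cycle and DNA replication genes were at 0.082 and -0.28. The values beside 4-OHT were small.

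Among 1638 identifiers without a symbol, which entered no list and no count of genes, 181 were at least 2-fold higher and 90 lower in the E2 library than in the vehicle library.

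The treatment named inside each table differed from the sample the archive attached it to, in 6 of 6 tables. If the archive record were right, the E2 library should hold the higher estrogen-induced genes under it, but their median log2 ratio over vehicle was -0.676 under the record and 1.80 under the names in the tables. Both values argue against the record and are consistent with libraries attached to the wrong samples there. The gene list cannot show which of the 2 libraries with 4-OHT is which, nor which of E2 and E2 plus PP2, since its levels were close within either pair (median 123 and 125 FPKM, and 242 and 234 FPKM). Nor does it settle vehicle and PP2 (47.1 and 77.8 FPKM) or vehicle and 4-OHT (47.1 and 123 FPKM), for which no direction was predicted. The E2 library stood above each of these, so it would stand above vehicle under either exchange. The PP2 and 4-OHT results therefore rest on the names in the tables alone.

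Interferon-stimulated genes were lower with 4-OHT than with vehicle (median log2 ratio -1.64). Lower depth is argued against by 25 members at 100 FPKM or more in the vehicle library, whose median was -1.22. Scaling between libraries is argued against because the setting that came nearest to 0 still gave -1.35. A single odd culture is argued against by E2 plus 4-OHT over E2, which shares no library with the first comparison, and had a median of -2.12, so that the nearer to 0 of both medians was -1.64. An effect of 4-OHT itself may account for it, as a hypothesis, while a shared difference in handling between the dishes with 4-OHT and the others was not tested.

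ATF4-CHOP stress genes were lower with PP2 alone (median log2 ratio -0.96). Lower depth of that library is argued against by 16 members at 100 FPKM or more, with a median of -1.02, and an unusually high vehicle library by PP2 over 4-OHT, with a median of -0.68. A single odd PP2 culture cannot be told apart from an effect of PP2, since 1 library held PP2 without E2. The lower level was not seen in the other library with PP2, since the median for E2 plus PP2 over E2 was -0.08. Both an effect of PP2 that is absent beside E2 and such a culture, fed or harvested otherwise, may therefore account for it.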

How the results depend on the processing

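The setting in which genes were picked in the pair with the inhibitor was chosen after the results were seen, and the others before. No paired analysis was possible because each group had 1 library, so no treatment was repeated across blocks. The 3 pairs with and without E2 could stand as repeats only if the inhibitors left the E2 response alone, which was the question, so no such fit was run. Among the settings other than the archive record, 81 of the counts of 2-fold genes stayed within 1.5 times and 31 moved further. List medians were run at both other pseudocounts, at 5 FPKM or more, centred and with the same upper quartile. Of these 796 stayed within the spread of the members divided by the root of their number, 43 moved and 1 reversed, where only lists outside the central range of random lists could count as reversed. Whatever their percentile, 24 medians turned sign with centring, the same upper quartile or a sum of 1000000, 1 of them under more than 1 of these, and most were near 0. For measures of the E2 response kept 23 stayed and 9 moved under the settings chosen before, and of 4 under the setting chosen after 2 stayed and 2 moved. With the archive record 1 count stayed and 13 moved, 4 medians of the estrogen-induced list moved and 3 reversed, and 8 measures of the E2 response moved. Depth limits the low genes. For the vehicle and E2 libraries the counting error of a log2 ratio at 5 FPKM was about 0.33, if 0.127 FPKM there is 1 read. The other libraries had relative depths of 0.677 to 0.883, so their error is larger. No replicate shows the error between cultures. The cause was not tested for any value that follows, except that a larger pseudocount or smaller values relative to it shrink the ratios of low genes by construction.

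With a pseudocount of 5, 899 genes were at least 2-fold higher for E2 over vehicle. The counts higher and lower were 252 and 269 for 4-OHT over vehicle, 105 and 127 for PP2 over vehicle, 2 and 0 for E2 plus 4-OHT over 4-OHT, 731 and 452 for E2 plus PP2 over PP2, and 69 and 113 for E2 plus PP2 over E2. For E2 plus 4-OHT over E2, 921 were lower. Beside 4-OHT r was 0.115, and 0.0% of higher and 0.0% of lower genes were kept. With a pseudocount of 0.1 the counts were 437 and 403 for PP2 over vehicle, 155 and 197 for E2 plus 4-OHT over 4-OHT, and 272 and 467 for E2 plus PP2 over E2. Beside 4-OHT r was 0.058, with 6.14% and 3.11% kept. With values summing to 1000000 970 genes were higher for E2 over vehicle, 781 were higher for E2 plus PP2 over PP2 and 998 lower for E2 plus 4-OHT over E2. The counts were 289 and 286 for 4-OHT over vehicle, 117 and 144 for PP2 over vehicle, 3 and 4 for E2 plus 4-OHT over 4-OHT, and 77 and 129 for E2 plus PP2 over E2.

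With genes at 5 FPKM or more the median of the estrogen-induced list was 1.14 for 4-OHT over vehicle and 0.64 for PP2 over vehicle. The counts were 8 and 14 for E2 plus 4-OHT over 4-OHT, r beside 4-OHT was 0.117, and 0.24% of higher and 0.477% of lower genes were kept. The median for markers of other cell types turned to -0.087 for E2 plus PP2 over E2, over fewer members. With genes picked in the pair with 4-OHT, 14.3% of higher and 7.87% of lower genes were also so without it, against 9.69% and 5.20% of all genes in that pair.

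With the archive record, E2 over vehicle had 502 genes higher and 476 lower, and the median of the estrogen-induced list reversed to -0.68. For 4-OHT over vehicle the counts were 77 and 89 with a median of 0.077, and for PP2 over vehicle 1700 and 706 with 1.074. For E2 plus 4-OHT over 4-OHT they were 1454 and 631 with 1.12. For E2 plus PP2 over PP2 they were 755 and 1614, and the median reversed to -1.24. For E2 plus 4-OHT over E2 they were 1332 and 627, and the median reversed to 2.29. For E2 plus PP2 over E2, 259 were higher and the median was 0.48. The E2 response beside 4-OHT then had a slope of 0.418 and r of 0.317, with 35.3% and 37.2% kept, and beside PP2 a slope of 0.243 and r of 0.178, with 28.5% and 37.4% kept.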

Other observations

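No hypothesis is tested in this part, and the genes named follow the rule fixed in advance unless said otherwise. Lipid and receptor lists each had members higher and members lower with E2. Of 11 measured genes of fatty acid synthesis and lipid storage, 9 were below the vehicle level with E2 (median -0.28, percentile 3.16). FASN, the fatty acid synthase, was at -1.37 and the droplet proteins PLIN4 and PLIN2 were at 1.71 and 1.02. Beside PP2 the same list had a median of -0.33, with FASN at -1.84 and ACLY, the citrate lyase, at -1.23. Of 22 sterol genes 4 were at least 2-fold higher with E2, including the LDL receptor LDLR (1.70), and DHCR24 was lower (-1.38); the median was 0.02, or -0.03 with ratios centred. Of 17 measured growth factor receptor genes 5 were at least 2-fold higher and 2 lower with E2 (median 0.43). Estrogen-repressed genes went both ways with E2, 4 of 18 at least 2-fold higher and 5 lower (median -0.21), with BCAS1 at -2.89 and CYP1B1 at 2.02. Aryl hydrocarbon receptor targets had 3 of 8 at least 2-fold higher (median 0.51), including TIPARP (1.71). Of 17 TNF family genes 7 were at least 2-fold higher (median 0.54, percentile 99.9), with TP63 at 4.51, while TNFRSF11B, the decoy receptor osteoprotegerin, was at 108 against 1056 FPKM (-3.28). Among Src family and adhesion genes 6 of 23 were at least 2-fold higher and 4 lower with E2 (median 0.30), with the kinases FRK (3.43) and FYN (2.67) higher and the integrin ITGB6 lower (-2.23).

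Further lists had small medians with E2. Interferon-stimulated genes were at least 2-fold higher in 7 of 34 (median 0.42, percentile 100), with HERC5 at 2.82. Early response genes had a median of 0.38. Oxidative stress genes had 1 of 16 at least 2-fold higher and 1 lower, GSR (-1.38), with a median of 0.32 (percentile 99.9), and endoplasmic reticulum chaperone genes had 20 of 23 above 0 (median 0.29), with XBP1 lower (-1.11). Survival genes had a median of -0.11, or 0.02 with the same upper quartile, and BIRC3 was the member at least 2-fold higher (1.67). Hypoxia and glycolysis genes had 5 of 18 at least 2-fold higher, including ADM (2.08), and 2 lower, with a median of -0.02 that turned to 0.11 with the same upper quartile and a mean of 0.16. Markers of other cell types were low in most members, with a median of 0.63 FPKM over 16 genes in the E2 library. Not low, and named after their values were seen, were the collagen COL1A1, at 60.2 FPKM with vehicle and 32.1 with E2, and HBA1, at 19.2 and 17.7, whose reads may belong to HBA2. The 7 measured had a median log2 ratio of 0.52 that turned to -0.10 with values summing to 1000000. CD68, a macrophage marker, was at 3.69 FPKM with E2 and 0.0324 with vehicle (2.19), and VWF, an endothelial marker, was at 34.9 FPKM with 4-OHT and 0.968 with vehicle (4.19). Reference genes had a median of 0.08, but UBC was at 8444 against 4007 FPKM with E2 (1.08).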
